A study of Rattus norvegicus with 27 samples.

How the data were processed

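Total RNA from rat hearts was biotin-labelled and hybridised to Illumina bead arrays, 27 of which are in the deposited table. Per the labels, 32 arrays were hybridised and the authors removed 5 with poor signal, leaving 7 for filtered air, 6 for coarse, 6 for fine and 8 for ultrafine particles. The authors preprocessed the scanner signals with lumi 1.5.17 at its default settings, and the range of the deposited values is that of a log2 scale. The exact lumi steps are not given in the sources used here. Whether the transform was a plain log2 or the variance stabilizing one of lumi, which compresses low values, is open, so each log2 difference and fold, above all of a dim probe, is on the scale of the table. In the values, the sorted levels of each array differed from those of filtered air 1 by 0.0185 at most, the mark of quantile normalization between arrays. All 27 columns of values matched a sample, and 0 per-sample columns were left unmatched. The lowest value of the table was 5.12 and the highest 14.17. Detection p-values, bead counts and background signals were not analysed here, so the number of arrays limits the precision and the signal over background of a probe is left open.

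Of the 22226 probes, 13192 carried 1 gene symbol, 0 carried several and 9034 carried none. Symbols were brought up to date by gene identifier against the RefSeq table of the GRCr8 assembly, used for names only. There 13151 matched and 41 did not. Per the labels, the authors kept 11657 probes detected on at least 1 array. The same number of probes was kept here by highest mean over all arrays, which put the filter at a mean of 5.79. Of these, 8031 carried a symbol, for 7952 genes, 77 of them with more than 1 probe, and 3626 probes were unnamed.

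The 4 groups were fitted in 1 linear model with lmFit and eBayes of limma 3.58.1 under R 4.3.3, on the deposited values, taken as log2, with no further normalization and no covariate. The tests are two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and a probe was called at an adjusted p under 0.05. The design names 3 comparisons with filtered air, 3 between particle sizes and 1 test of any difference among the groups. Counts at the authors' thresholds, a fold over 1.5 with a false discovery rate under 5% or 25%, stand beside them. There were 45 gene lists for pathways, complexes and cell types, fixed with the comparisons, the panel of 20 genes and the rule for named genes before the data were examined. Of these, 43 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with fry, and with an exact permutation test of the list mean per array between the groups compared. The adjusted p of a list is over the 43 lists of a comparison. One probe per gene, that with the smallest p, stood for a gene in the named genes.

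Genes were named by rule. For each particle size against filtered air these are the 10 highest and 10 lowest log2 differences among genes called, filled up to 10 from genes with a fold over 1.5 and a false discovery rate under 25%, and then up to 5 in each direction by smallest p, the latter given as values only. For each pair of sizes they are the 5 highest and 5 lowest differences called. Up to 4 called members of each list, the 3 members with the smallest p of each list called, and the panel were added. Probes with no gene symbol were counted and not named. The beta oxidation genes Acadm, Hadhb and Acadvl, Mlycd with ultrafine particles, Pdk4 and Cyp2e1 with fine particles, the glycolysis genes called between fine and ultrafine particles, and single genes given for single arrays fall outside this rule and were chosen after their values were seen.

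Sets of arrays were examined by correlation and by the means of the lists. An array was taken as standing apart where its mean over the lymphocyte list lay over 3 median absolute deviations above the median of all arrays, or where its median correlation with the other arrays lay more than 1.5 interquartile ranges below the first quartile, a limit of 0.949. This rule, the 20 arrays it leaves, the second use of the rule for named genes in them, the lists tested between particle sizes, the differences of list means with 1 array left out, and the thymocyte and adipocyte means as covariates were chosen after seeing the data. Alternatives tried were no filter, the brighter of the kept probes (those above their median), other normalizations between arrays, 1 probe per gene, a mean-variance trend with robust fitting, array weights, the replicate number as a block, fits of the compared groups alone, each array left out in turn, and separate control arrays for each side of a correlation. No pseudocount was tried, because the deposited values are already on a log2-like scale. For each count, 100 regroupings of the arrays into groups of the same sizes, the real grouping among them, were fitted the same way.

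The fit was tested on simulated data in which known probes were shifted and the noise was independent between probes and arrays. The shares called may therefore differ in the real arrays. Of probes shifted by 0.5 on the log2 scale, 72% for coarse, 67% for fine and 75% for ultrafine particles were called in 27 arrays, and 81%, 88% and 82% in the 20 arrays. Of probes shifted by 1, between 93% and 100% were called. False calls numbered 3 to 11. Of 2 lists that held a shifted gene 1 was called, and of 41 others 0. Because the simulated genes were independent, this does not show how often camera makes false calls in the real arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Hepatocyte and lung epithelial markers had fewer than 5 measured genes, 2 and 3, and were not tested. Particle doses, dates, array slides and animal identities are not in the labels and were not analysed here.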

Results

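The levels of 22226 probes were measured with Illumina rat bead arrays in total RNA from whole hearts of male Fisher 344 rats. The rats were 4 weeks old at the start and inhaled filtered air, or coarse, fine or ultrafine ambient particles, for 3 months. The deposited table held 27 arrays, 7 of filtered air, 6 of coarse, 6 of fine and 8 of ultrafine particles, each taken as 1 rat. The question, as the series title gives it, was whether long exposure to particles alters gene expression in the heart, and each particle size was compared with filtered air and with the other sizes. The levels ran from 5.12 to 14.17 over all arrays and were taken as log2, but whether low values were compressed by a variance stabilizing transform is open, which bears on the folds of dim probes. The number of arrays limits the precision. Each p-value below of a gene, of fry or of the permutation test measures a difference against the spread between these rats. A camera p-value sets the genes of a list against the other genes instead, at a preset or an estimated correlation between genes. At the preset correlation it does not measure the spread of the list mean between rats.

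The arrays did not all hold the same mixture of cells. The mean of 22 measured lymphocyte and mast cell markers lay between 5.55 and 8.32 median absolute deviations above the median of all arrays on filtered air 1, coarse 1, coarse 2, ultrafine 2 and ultrafine 7. It lay 3.76 above on fine 2. The highest of the other arrays, coarse 5, lay 1.81 above. Cd3d, a chain of the T cell receptor complex, stood at 11.01 on filtered air 1, 12.16 on coarse 1, 10.67 on coarse 2, 9.57 on fine 2, 11.57 on ultrafine 2 and 12.08 on ultrafine 7, against a median of 6.39 over all arrays. Rag1, which recombines antigen receptor genes in immature lymphocytes, stood between 8.31 and 11.28 on these 6 arrays, against a median of 5.72. Dntt, which adds nucleotides during the same step, stood between 6.53 and 9.21 against a median of 5.79. The plot of lymphocyte markers on each array shows this separation for the list mean, Cd3d and Rag1. Ultrafine 8 stood apart in another way: its median correlation with the other arrays was 0.913, below a limit of 0.949 set from the quartiles of all arrays. Coarse 1, at 0.904, ultrafine 7, at 0.903, and ultrafine 2, at 0.945, also lay below that limit.

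**Figure D1:**
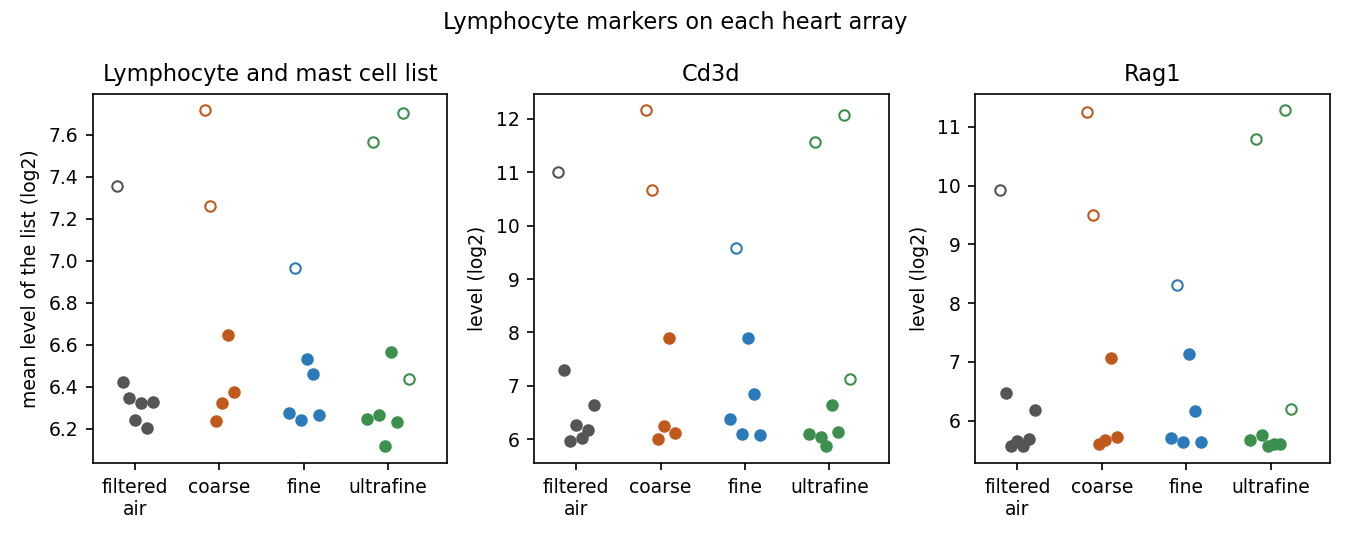
Mean level of the lymphocyte and mast cell list and levels of Cd3d and Rag1 (vertical axes, log2) on each of the 27 heart arrays by group (horizontal axis), 1 circle per array, open for the 7 arrays that stood apart. The 6 arrays high in these markers held Cd3d between 9.57 and 12.16, against a median of 6.39 over all arrays.

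Because lymphocyte genes varied this much between arrays of 1 group, each comparison was also made in the 20 arrays left without these 7: 6 of filtered air, 4 of coarse, 5 of fine and 5 of ultrafine particles. That exclusion was chosen after seeing the data, and a set of 6 arrays picked by eye had been tried before its rule was written. Values from all 27 arrays come first below, and values from the 20 arrays are named as such.

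In hearts of rats that breathed coarse particles, Cyp2e1, a cytochrome P450 that oxidises ethanol, acetone and small solvents, rose 1.79-fold over filtered air. Its level was 8.14 ± 0.07 (SD, n = 6) against 7.31 ± 0.29 (SD, n = 7), a log2 difference of 0.84 with a standard error of 0.13 and an adjusted p of 0.0185. It was higher in 6 of 6 coarse arrays than the filtered air mean. It was the only 1 of 11657 probes called by limma in this comparison, while 475 had an unadjusted p under 0.05. At the authors' looser threshold, a fold over 1.5 with a false discovery rate under 25%, Fbxl22, a ubiquitin ligase subunit of heart and skeletal muscle, was 1.65-fold lower. Ccnd1, which encodes cyclin D1, was 1.52-fold lower, each with an adjusted p of 0.21 and each lower in 6 of 6 arrays. The next genes by p, Slc3a2, the heavy chain of several amino acid transporters, at 0.31, Slc22a3, an organic cation transporter, at 0.28, Ddn, which encodes dendrin, at -0.46, and Hba-a1, an alpha globin, at -0.31, did not pass, with adjusted p of 0.21 each. The call of Cyp2e1 was lost when filtered air 2 or 3 or coarse 1, 2, 3, 5 or 6 was left out, with adjusted p up to 0.0823, and in a fit of the 2 groups alone, at 0.0664.

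Of 43 gene lists tested for coarse particles, 9 were called by camera in all 27 arrays, and none of the 9 with an estimated correlation, by fry or by the exact permutation test. Collagens and extracellular matrix genes fell, with 25 of 27 measured members below 0, a median of -0.26 and an adjusted p of 1.95e-05, or adjusted p = 0.686 with an estimated correlation. Among them Col1a2 stood at -0.46, Col14a1 at -0.45 and Lamc1 at -0.34, and no member was called over all probes or adjusted over the list alone. Macrophage markers rose, with 19 of 22 members positive, a median of 0.15 and an adjusted p of 0.00023, or adjusted p = 0.686 with an estimated correlation. The scavenger receptor gene Cd163 stood at 0.26 and the complement genes C1qb at 0.34 and C1qa at 0.21. Here 1 member passed when adjusted over the list alone and 0 over all genes. Both calls held without each array in turn, with adjusted p up to 0.00822 and 0.00411, but the difference of the collagen list mean shrank from -0.24 to -0.12 without coarse 1. The collagen median was -0.13 in the 20 arrays.

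The other lists called for coarse particles depended on single arrays, coarse 1 above all. Coarse 1 was the array highest in lymphocyte markers, with a list mean of 7.72. Its sarcomere list mean was 11.35, against 12.08 to 12.31 with filtered air. Calls and shifts that rested on coarse 1 can therefore not be told apart from a larger share of other tissue on that array. Calcium handling and ion channel genes fell (16 of 18 below 0, median -0.18, adjusted p 0.00399), with the potassium channel genes Kcnd2 at -0.58 and Kcnd3 at -0.42 and the calcium channel subunit gene Cacnb2 at 0.23. Adjusted over the list alone 1 member passed higher and 2 lower, against 0 over all genes. Sarcomere genes fell (12 of 13 below 0, median -0.18, adjusted p 0.00945), with Actc1 at -0.47, Ldb3 at -0.66 and Tnni3 at -0.19. For both lists adjusted p = 0.686 with an estimated correlation. Without coarse 1 neither was called, with an adjusted p of 0.228 each. Genes of the mitochondrial respiratory chain fell (38 of 47 below 0, median -0.11, adjusted p 0.018) and those of cytosolic ribosomal proteins rose (48 of 55 positive, median 0.08, adjusted p 0.0125), for both adjusted p = 0.782 with an estimated correlation. Both turned direction without coarse 1, at adjusted p of 0.263 and 0.252. The ribosomal call was also lost without filtered air 2, filtered air 7 or coarse 2. Cycs, the gene of cytochrome c, stood at -0.30, Sdhc at -0.35, Rpl35 at 0.41 and Rps16 at 0.16.

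Inflammatory genes rose as a list (21 of 29 positive, median 0.13, adjusted p 0.0184; adjusted p = 0.686 with an estimated correlation), with Cd14 at 0.19, Ccl20 at 0.13 and the chemokine gene Cxcl1 at -0.15. The call was lost without filtered air 7 or coarse 1, at adjusted p up to 0.264. White and brown adipocyte markers rose (11 of 15 positive, median 0.15, adjusted p 0.0267; adjusted p = 0.721 with an estimated correlation), with the lipase genes Lipe at 0.59 and Pnpla2 at 0.54 passing adjusted over the list alone, 2 members, against 0 over all genes. That call was lost without filtered air 2, 4 or 6 or coarse 1, 2 or 6, at adjusted p up to 0.215. Skeletal muscle markers rose (7 of 8 positive, median 0.37, adjusted p 0.0464; adjusted p = 0.721 with an estimated correlation). One array, coarse 6, held Tnnt3 at 8.65 and Myl1 at 8.63, and without it the direction turned, at an adjusted p of 0.702. The skeletal muscle call was kept in 14 of 27 such fits and also lost without filtered air 2, 6 or 7, fine 1, 2 or 6, or ultrafine 1, 2, 4, 6, 7 or 8. Of these 9 lists, 5 were not called without the 7 arrays. These were calcium handling, with an adjusted p of 0.0652, sarcomere genes, with 0.0927 and 7 of 13 members positive, inflammatory genes, with 0.263, adipocyte markers, with 0.613, and the respiratory chain. The last list was positive there for 34 of 47 members, with an adjusted p of 0.0753.

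With coarse particles in the 20 arrays, Pdk4, a kinase that shuts off pyruvate dehydrogenase and so spares glucose, rose 3.00-fold over filtered air, from 7.84 ± 0.50 (SD, n = 6) to 9.43 ± 0.44 (SD, n = 4), with a standard error of 0.24 for the log2 difference of 1.58 and an adjusted p of 0.00384. Penk, the precursor of the enkephalins, rose 2.16-fold, Rbp7, a retinol binding protein of endothelium and fat, 1.82-fold, Gpihbp1, which anchors lipoprotein lipase to capillaries, 1.64-fold, and Cyp2e1 1.67-fold. The lipase genes Lipe and Pnpla2 rose by 0.67 and 0.61, Aqp7, a glycerol channel, by 0.53, and Colq, the collagen tail of acetylcholinesterase, by 0.53. Acot1, a thioesterase of fatty acyl-CoA and a known target of the fatty acid receptor PPAR alpha, rose by 0.52 and Cbr1, a carbonyl reductase, by 0.49. Slc2a4, the insulin-responsive glucose transporter, was 1.51-fold lower, Atcay, which encodes caytaxin, 1.61-fold lower and Fbxl22 1.57-fold lower. Tuba8, an alpha tubulin, fell by 0.51, Higd1a, a hypoxia-induced mitochondrial gene, by 0.48, and Apln, the apelin precursor, by 0.47. Slc25a29, a mitochondrial carrier of basic amino acids, fell by 0.45, Lmod3, an actin filament nucleator of muscle, by 0.41, Ddn by 0.39, Emc9 by 0.38 and Hba-a1 by 0.36. Each of these genes lay on the same side of the filtered air mean in 4 of 4 coarse arrays, with adjusted p between 0.00114 and 0.0325.

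There were 44 probes called for coarse particles in the 20 arrays, 29 higher and 15 lower, 35 of them with a gene name, and 1074 had an unadjusted p under 0.05. All 44 had the same sign in the 27 arrays, where 1 was called. The count fell to 23 without coarse 4, 26 without coarse 3 and 28 without coarse 5, and was 70 without ultrafine 5.

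Of the lists in the 20 arrays, fatty acid oxidation genes and PPAR targets rose with coarse particles, with 27 of 30 members positive, a median of 0.18 and an adjusted p of 8.78e-08, or adjusted p = 0.531 with an estimated correlation. Over all genes 2 members, Pdk4 and Acot1, were called, and 9 passed adjusted over the list alone. Mlycd, which removes malonyl-CoA, stood at 0.62 with an adjusted p of 0.0837. The groups overlapped: the list mean was 9.87 on coarse 5, below filtered air 6 at 9.97 and 7 at 9.95. It was 10.00 to 10.21 on coarse 3, 4 and 6 and 9.65 to 9.79 on filtered air 2 to 5. Pdk4 also stood higher on filtered air 6 and 7, at 8.48 and 8.36, than on filtered air 2 to 5, at 7.25 to 7.94. The cause of that split among controls was not tested. The exact permutation test of the list mean gave a p of 0.0286, where these group sizes allow none under 0.00476, so that 1 list alone could not pass over 43. In all 27 arrays the same list had a median of -0.01, a mean of 0.08, an upward test direction and an adjusted p of 0.0843, with 4 members higher adjusted over the list alone and 0 called over all genes. The white and brown adipocyte list had a median of -0.05 and a mean of -0.06 in the 20 arrays beside an upward test direction, with an adjusted p of 0.613, although Lipe and Pnpla2 belong to it.

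A further 6 lists were called for coarse particles in the 20 arrays. Xenobiotic metabolism genes and targets of the aryl hydrocarbon receptor rose (8 of 11 positive, median 0.25, adjusted p 0.00854; adjusted p = 0.379 with an estimated correlation), with Cyp2e1 called over all genes and 3 members passing adjusted over the list alone. Por, the reductase that feeds electrons to P450 enzymes, stood at 0.25 and Cyp4b1 at 0.37. The mean of this list was 7.47 on filtered air 6 and on 7, above coarse 5 at 7.46 and coarse 6 at 7.43. Enzymes and scavengers of reactive oxygen species rose (21 of 29 positive, median 0.08, adjusted p 0.00854; adjusted p = 0.154 with an estimated correlation), also by fry at an adjusted p of 0.025. Glrx, a glutaredoxin, stood at 0.30, Prdx2 at 0.19 and Gpx4 at 0.15, with 0 members called over all genes and 1 adjusted over the list alone. Macrophage markers rose (18 of 22 positive, adjusted p 0.00854; adjusted p = 0.702 with an estimated correlation), but not without filtered air 2 or coarse 5, at adjusted p up to 0.0994. Collagens and matrix genes fell (18 of 27 below 0, adjusted p 0.0124; adjusted p = 0.654 with an estimated correlation), but not without filtered air 2 or 5 or coarse 3 or 4, at adjusted p up to 0.217. Ribosomal protein genes fell here (36 of 55 below 0, adjusted p 0.00297; adjusted p = 0.654 with an estimated correlation), opposite to their direction in all 27 arrays, and the call was lost without coarse 3, at 0.0523. The skeletal muscle list rose (7 of 8 positive, adjusted p 0.0206; adjusted p = 0.702 with an estimated correlation), but not without filtered air 6 or coarse 6, at adjusted p up to 0.669.

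With fine particles no gene passed the test. The genes with the smallest p were Ncl, which encodes the ribosome assembly protein nucleolin, at -0.44 with a standard error of 0.10, Sra1, a steroid receptor coactivator, at 0.26, Csnk1d, a casein kinase, at 0.25, Cptp, a lipid transfer protein, at 0.31, Rnasek at 0.42 and Lrrc41 at 0.33. Lower in rank were the anti-inflammatory annexin gene Anxa1 at -0.53, the translation factor gene Eif3a at -0.49, Nol8 at -0.32 and Gtf2h1 at -0.27. Each of these 10 genes lay on the same side of the filtered air mean in 6 of 6 fine arrays, and their adjusted p ran from 0.405 to 0.737. The count by limma was 0 of 11657, with 697 probes at an unadjusted p under 0.05. It was 0 also with a mean-variance trend and robust fit and 19 with array weights. In a test on simulated data, 67% of probes shifted by 0.5 and 94% of probes shifted by 1 on the log2 scale were called for fine particles, with 3 false calls. The simulated noise was independent between probes and arrays and held no array that stood apart, so the share in the real arrays may differ.

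The count for fine particles was again 0 in the 20 arrays by limma, by its trend and robust fit and with array weights, with 1417 probes at an unadjusted p under 0.05 and a lowest adjusted p of 0.19. The genes with the smallest p were Irf2bp1 at 0.33, Psmb5, a catalytic proteasome subunit, at 0.40, Syngr1 at 0.31, Pskh1 at 0.27, Gnpat, an enzyme of ether lipid synthesis, at 0.26, Ncl at -0.43, Dnajc2 at -0.27, C1qtnf2 at -0.27 and Mcmdc2 at -0.24, each with an adjusted p of 0.19, and Eif3a at -0.48 with an adjusted p of 0.205. Pdk4, at 0.08, and Cyp2e1, at -0.10, did not pass in this comparison.

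No gene list was called by camera for fine particles in either set of arrays, nor by fry. Genes of glycolysis and glucose uptake were positive for 15 of 17 members in all 27 arrays, with a median of 0.11, a camera adjusted p of 0.336 and an exact permutation p of 0.00233, adjusted to 0.1. Of the 17 members, 13 were positive in the 20 arrays, with a camera adjusted p of 0.0582 and an exact permutation p of 0.00217, the smallest these group sizes allow, adjusted to 0.0931. Adjusted over the list alone 2 of its members passed there, against 0 over all genes. For targets of Nrf2, the regulator of antioxidant genes, and genes of glutathione metabolism, 20 of 27 members were positive in all 27 arrays, with a camera adjusted p of 0.336 and an exact permutation p of 0.00758, adjusted to 0.163.

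With ultrafine particles, Txnip, an inhibitor of thioredoxin and of glucose uptake, rose 1.79-fold over filtered air. Its level was 12.49 ± 0.26 (SD, n = 8) against 11.65 ± 0.17 (SD, n = 7), a log2 difference of 0.84 with a standard error of 0.16 and an adjusted p of 0.0293, and it was higher in 8 of 8 ultrafine arrays. Cyp2e1 rose 1.57-fold, higher in 7 of 8 arrays, with an adjusted p of 0.0354. Epb41, a protein of the membrane skeleton, rose by 0.51, Acot1 by 0.47, Rnase1, a ribonuclease secreted by endothelium, by 0.41, Impa2, an inositol monophosphatase, by 0.35 and Slc3a2 by 0.33, each higher in 8 of 8 arrays. Ddn fell by 0.46, from 6.73 ± 0.16 (SD, n = 7) to 6.27 ± 0.19 (SD, n = 8), with a standard error of 0.09, and was lower in 8 of 8 arrays. Adjusted p of these 8 probes ran from 0.0293 to 0.0456, and the plot of 6 gene levels shows 4 of them on every array.

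**Figure D2:**
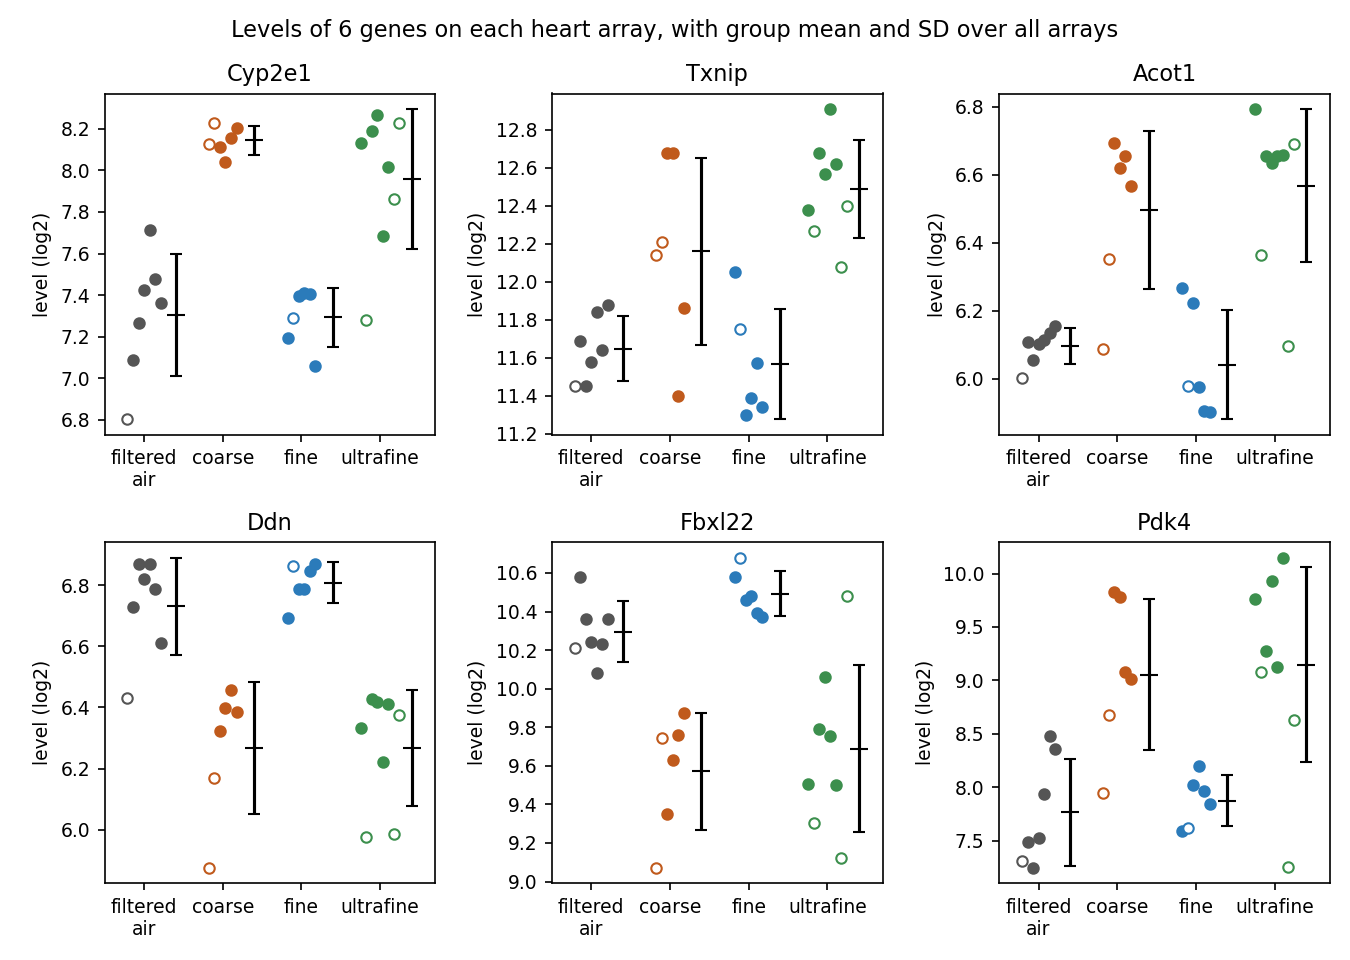
Levels of Cyp2e1, Txnip, Acot1, Ddn, Pdk4 and Fbxl22 (vertical axes, log2) on each of the 27 heart arrays by group (horizontal axis), 1 circle per array, open for the 7 arrays that stood apart, with the group mean as a horizontal mark and the SD over all arrays of the group as a vertical line. Cyp2e1 had a mean of 8.14 with coarse particles against 7.31 with filtered air, and Txnip 12.49 with ultrafine particles against 11.65.

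These 8 were all the probes called by limma for ultrafine particles, 7 higher and 1 lower, and 615 had an unadjusted p under 0.05. Further genes met the authors' looser threshold, among them Pdk4, 2.61-fold higher with an adjusted p of 0.155, Angptl4, an inhibitor of lipoprotein lipase, at 0.74 with 0.114, Lipe at 0.69 with 0.209, Atcay at -0.83 with 0.0601, Tuba8 at -0.73 with 0.0644 and Fbxl22 at -0.60 with 0.189. Slc25a38, a mitochondrial glycine carrier, stood at -0.35 with an adjusted p of 0.091. The count was 0 without any 1 of filtered air 2, 3, 4, 5, 6 or 7 or of ultrafine 4, 2 without ultrafine 5, 4 without ultrafine 1 or 3, 5 without filtered air 1 and 21 without ultrafine 7, and 0 with a mean-variance trend and robust fit. With the replicate number as a fixed block it was 12, 2 higher and 10 lower, and 2 of the 8 calls were kept.

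Of 43 lists, 11 were called by camera for ultrafine particles in all 27 arrays, and none with an estimated correlation, by fry or by the exact permutation test. Collagens and matrix genes fell, with 26 of 27 members below 0, a median of -0.25 and an adjusted p of 1.10e-06, or adjusted p = 0.514 with an estimated correlation. Col1a1 stood at -0.67, Col1a2 at -0.43 and Lamc1 at -0.35. Macrophage markers rose (19 of 22 positive, median 0.14, adjusted p 0.000404; adjusted p = 0.514 with an estimated correlation), with Cd163 at 0.23, Fcgr3a at 0.20 and Lgals3 at 0.54 and 1 member passing adjusted over the list alone, against 0 over all genes. Glycolysis and glucose uptake genes fell (14 of 17 below 0, median -0.17, adjusted p 0.000512; adjusted p = 0.514 with an estimated correlation), with Slc2a4 at -0.81, Pgam2 at -0.54 and the hexokinase gene Hk2 at -0.36, and 1 member passing adjusted over the list alone, against 0 over all genes. Calcium handling genes fell (15 of 18 below 0, median -0.19, adjusted p 0.000404; adjusted p = 0.536 with an estimated correlation), with Kcnip2 at -0.60, Hcn2 at -0.31 and Jph2 at -0.24. Sarcomere genes fell (12 of 13 below 0, adjusted p 0.0018; adjusted p = 0.514 with an estimated correlation). Xenobiotic metabolism genes rose (8 of 11 positive, median 0.12, adjusted p 0.0139; adjusted p = 0.514 with an estimated correlation), with Cyp2e1 called, 2 members passing adjusted over the list alone, and Fmo1 and Sult1a1 at 0.38 each. These 6 calls held without each array in turn, but list means moved. Without ultrafine 7 the difference of the mean shrank from -0.25 to -0.15 for collagens, from -0.18 to -0.09 for calcium handling and from -0.23 to -0.15 for sarcomere genes, and without ultrafine 8 from 0.15 to 0.09 for xenobiotic metabolism. Ultrafine 7 was the ultrafine array highest in lymphocyte markers, at 7.71, with a sarcomere list mean of 11.38. Ultrafine 8, not high in these markers, held 11.49. What rested on ultrafine 7 can therefore not be told apart from a larger share of other tissue on it. Only the macrophage and xenobiotic metabolism lists were called again without the 7 arrays. There the adjusted p was 0.0883 for collagens, 0.142 for calcium handling, 0.185 for glycolysis, with a median of -0.01, and 0.887 for sarcomere genes, with 7 of 13 members positive.

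The other 5 calls for ultrafine particles did not. Fetal and hypertrophy genes fell (9 of 10 below 0, median -0.38, adjusted p 0.00235; adjusted p = 0.536 with an estimated correlation), with Acta1 at -0.78, the natriuretic peptide gene Nppb at -0.63 and Ccn2 at -0.39, but not without ultrafine 7, at 0.0636. Respiratory chain genes fell (43 of 47 below 0, median -0.10, adjusted p 0.000404; adjusted p = 0.656 with an estimated correlation), with Ndufb7 at -0.59 and Cycs at -0.34, but not without ultrafine 7, at 0.351. Fibroblast markers fell (12 of 17 below 0, adjusted p 0.024; adjusted p = 0.656 with an estimated correlation), with Ogn at -0.56, but not without filtered air 5, ultrafine 2 or ultrafine 7, at up to 0.195. Cholesterol and fatty acid synthesis genes fell (14 of 18 below 0, median -0.09, adjusted p 0.0139; adjusted p = 0.514 with an estimated correlation), with Sc5d at -0.34, Sqle at -0.17 and Cyp51 at -0.15, but not without filtered air 1, 3 or 5 or ultrafine 1, 3 or 8, at up to 0.0629. Inflammatory genes rose (22 of 29 positive, median 0.11, adjusted p 0.0486; adjusted p = 0.536 with an estimated correlation), with Il1b at 0.25, Myd88 at 0.15 and Cxcl1 at -0.16, and the call was kept in 12 of 27 fits that left out 1 array. It was lost without filtered air 2, 3, 6 or 7, coarse 4 or 6, fine 1, 2, 4, 5 or 6, or ultrafine 2, 3, 5 or 7. Of these 5 lists only cholesterol and fatty acid synthesis was called again without the 7 arrays. The respiratory chain list was negative there for 26 of 47 members, with a median of -0.02, an upward test direction and an adjusted p of 0.895. The adjusted p was 0.368 for fetal, 0.977 for fibroblast and 0.11 for inflammatory genes.

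With ultrafine particles in the 20 arrays, Pdk4 rose 3.50-fold over filtered air, from 7.84 ± 0.50 (SD, n = 6) to 9.65 ± 0.44 (SD, n = 5), with a standard error of 0.23 for the log2 difference of 1.81 and an adjusted p of 0.000306. Penk rose 2.00-fold, Rbp7 1.99-fold, Txnip by 0.95, Angptl4 by 0.95, Lipe by 0.94 and Fitm2, which forms lipid droplets, by 0.78. Gpihbp1 rose by 0.71, Aqp7 by 0.70, Colq by 0.69, Cyp2e1 by 0.67 and Cbr1 by 0.62. Pnpla2 rose by 0.61, Cpt1a, which carries long-chain fatty acids into mitochondria, by 0.60, Ucp3, a mitochondrial uncoupling protein, by 0.59, Cldn5, of endothelial tight junctions, by 0.59 and Acot1 by 0.57. Hmox1, the haem oxygenase induced by oxidative stress, rose by 0.34, from 6.94 ± 0.11 (SD, n = 6) to 7.28 ± 0.05 (SD, n = 5), with an adjusted p of 0.0334. Slc40a1, the iron exporter ferroportin, rose by 0.31 and Fcgr2a, an Fc receptor gene, by 0.30. Sqstm1, an autophagy receptor, rose by 0.53 on 1 probe and stood at 0.14 on its other probe.

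Other genes fell with ultrafine particles in the 20 arrays. Slc2a4 was 1.60-fold lower, from 9.80 ± 0.15 (SD, n = 6) to 9.12 ± 0.22 (SD, n = 5), with an adjusted p of 0.000306, Atcay 1.63-fold lower and Tuba8 1.59-fold lower. Esm1, an endothelial proteoglycan, fell by 0.65, Bdh1, which oxidises ketone bodies, by 0.61, Slc25a29 by 0.59 and Fbxl22 by 0.58. The tubulin gene Tuba4a fell by 0.47, Ddit3, a transcription factor of the stress of the endoplasmic reticulum, by 0.47, Higd1a by 0.45, Apln by 0.37 and Sqle, of cholesterol synthesis, by 0.31. Each called gene named so far for the 20 arrays of this comparison lay on the same side of the filtered air mean in 5 of 5 ultrafine arrays. The limma count was 84, 56 higher and 28 lower, 75 of them with a gene name, and 1086 had an unadjusted p under 0.05. Of these, 83 had the same sign in all 27 arrays, where 8 were called, and all 8 were among the 84. The count was 55 without filtered air 7.

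Fatty acid oxidation genes and PPAR targets rose with ultrafine particles in the 20 arrays, with 19 of 30 members positive, a median of 0.12 and an adjusted p of 3.63e-06, or adjusted p = 0.577 with an estimated correlation. On ultrafine 5 the list mean was 9.57, below all 6 filtered air arrays (9.65 to 9.97), against 10.01 to 10.21 on the other 4 ultrafine arrays. The difference of the list mean was 0.22, or 0.33 without ultrafine 5. Over all genes 6 members were called, Pdk4, Acot1, Cpt1a, Ucp3, Angptl4 and Mlycd, the last at 0.61 and higher in 4 of 5 arrays, and 8 passed adjusted over the list alone. The exact permutation test of the list mean gave a p of 0.106, where these group sizes allow none under 0.00217 and 1 list alone could not pass either. Acadm stood at -0.09, Hadhb at -0.03 and Acadvl at 0.13, none called, 3 genes picked after their values were seen in the plot of the list's genes. In all 27 arrays the list had a median of -0.03, a mean of 0.08 and an upward test direction, with an adjusted p of 0.0891, 1 member called and 5 passing adjusted over the list alone.

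**Figure D3:**
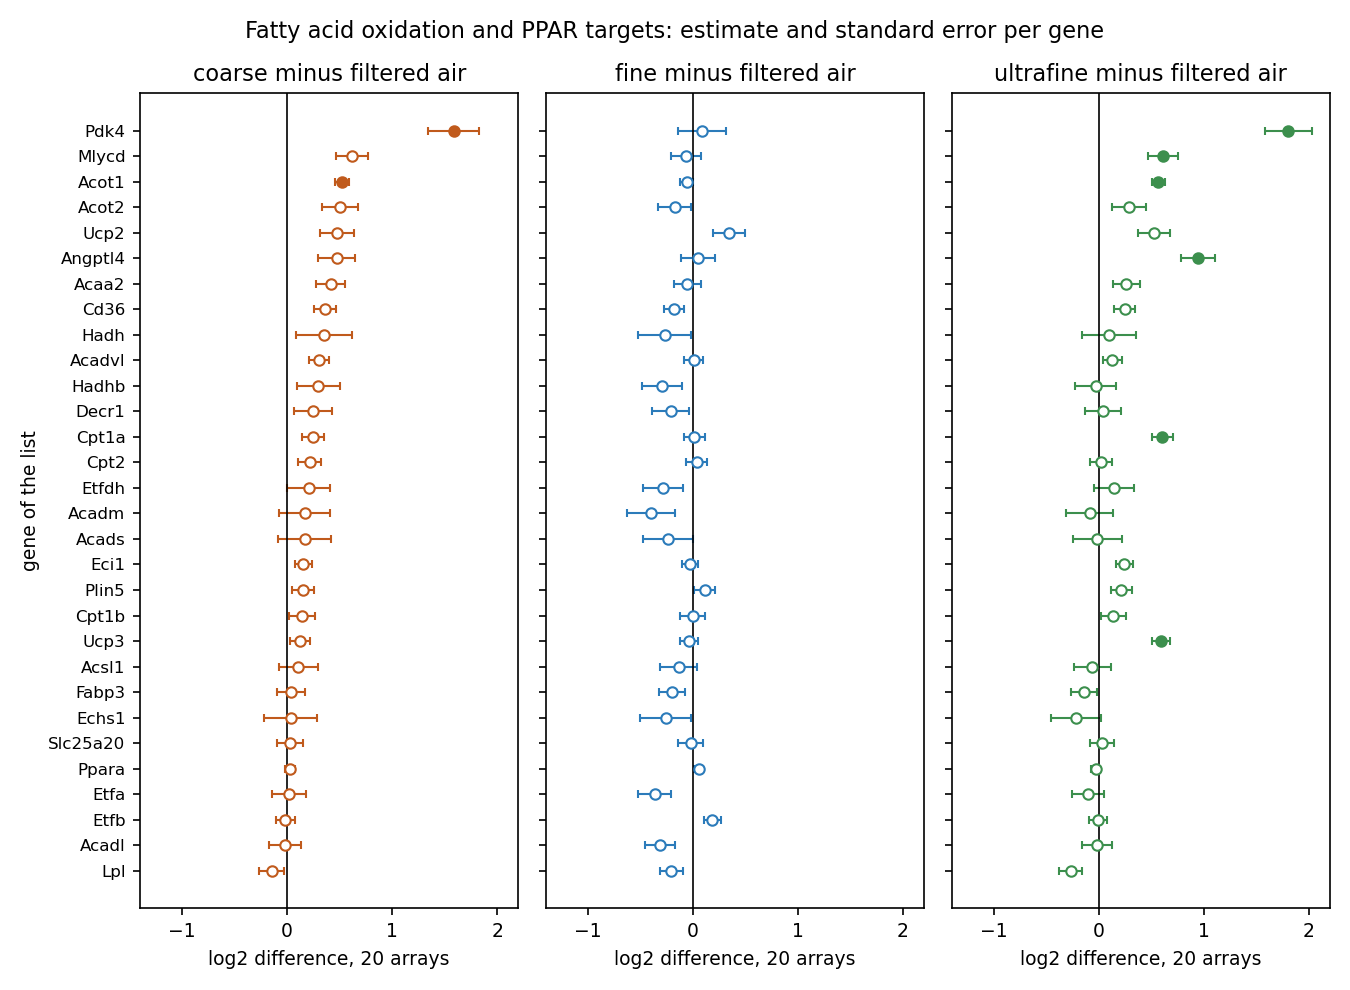
Log2 difference from filtered air (horizontal axis) of each gene of the fatty acid oxidation and PPAR target list (vertical axis) for coarse, fine and ultrafine particles in the 20 arrays, points with standard errors, filled where adjusted p was under 0.05. Pdk4 stood at 1.58 with coarse, 0.08 with fine and 1.81 with ultrafine particles, and Acot1 at 0.52, -0.06 and 0.57.

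A further 5 lists were called for ultrafine particles in the 20 arrays. Cholesterol and fatty acid synthesis genes fell (17 of 18 below 0, median -0.15, adjusted p 0.000895; adjusted p = 0.342 with an estimated correlation), with Sqle called and 4 members lower adjusted over the list alone. The exact permutation test of this list mean gave a p of 0.16. The mean was 6.84 to 6.94 on filtered air 2, 4 and 6, within the 6.73 to 7.05 of the ultrafine arrays. It was higher on filtered air 3, 5 and 7, at 7.33, 7.40 and 7.18. Xenobiotic metabolism genes rose (8 of 11 positive, median 0.13, adjusted p 0.0123; adjusted p = 0.331 with an estimated correlation), with Cyp2e1 called, and adjusted over the list alone 3 members passed higher and 1, Nqo1 at -0.16, lower. Both calls held without each array in turn. The xenobiotic list mean was 7.47 on filtered air 6 and on 7, above ultrafine 3 at 7.40 and ultrafine 4 at 7.46. It was 7.20 to 7.30 on filtered air 2 to 5. Macrophage markers rose (18 of 22 positive, adjusted p 0.0116; adjusted p = 0.664 with an estimated correlation), with Fcgr2a called and passing adjusted over the list alone, 1 member, but not without filtered air 2 or ultrafine 5, at up to 0.77. Endothelial markers rose (12 of 17 positive, median 0.07, adjusted p 0.0204; adjusted p = 0.331 with an estimated correlation), with Cldn5 called, 4 members higher adjusted over the list alone, Esam at 0.29 and Tie1 at 0.27, or 0.13 on its other probe, but not without ultrafine 5, at 0.153. Erythrocyte genes rose (8 of 11 positive, median 0.15, adjusted p 0.0384; adjusted p = 0.588 with an estimated correlation), with Hbb-b1 at 0.93, Ahsp at 0.83 and Alas2 at 0.65, none called, but not without filtered air 2 or ultrafine 5, at up to 0.246. With array weights these last 3 lists were not called, at 0.336, 0.187 and 0.299. Alas2, an enzyme of haem synthesis in red cell precursors, stood at 8.26 on ultrafine 5. The white and brown adipocyte list had a median of -0.04 and a mean of -0.02 beside an upward test direction, with an adjusted p of 0.612.

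Coarse and fine particles were set against each other in the same fit. Cyp2e1 was 1.80-fold higher with coarse particles, at 8.14 ± 0.07 (SD, n = 6) against 7.29 ± 0.14 (SD, n = 6), with a standard error of 0.14 and an adjusted p of 0.0262. Fbxl22 was 1.89-fold lower and Ddn 1.45-fold lower, each with an adjusted p of 0.0315, and each of the 3 genes lay on its side of the fine mean in 6 of 6 coarse arrays. These were the 3 probes called by limma, with 767 at an unadjusted p under 0.05, and the count was 0 without any 1 of coarse 1 to 4 or fine 1 to 6, and 8 without ultrafine 7 or 8. Without the 7 arrays 32 probes were called, 16 in each direction, all with the same sign in the 27 arrays. Pdk4 was higher with coarse particles by 1.50, Rbp7 by 1.13, Ivns1abp by 0.87, Cyp2e1 by 0.83 and Penk by 0.80. Fbxl22, Tuba8, Wfdc1, Slc2a4 and Atcay were lower, by a fold of 1.74 for Fbxl22 and log2 differences of -0.72, -0.68, -0.67 and -0.66, with adjusted p from 0.00139 to 0.0324 and 4 of 4 arrays each. That count was 12 without coarse 3, 15 without coarse 4 and 21 without fine 6.

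Lists between the sizes were tested in comparisons added after seeing the data, and 11 were called between coarse and fine particles in all 27 arrays and 9 in the 20 arrays. Glucocorticoid-responsive genes were higher with coarse than with fine particles in all 27 arrays (8 of 12 positive, median 0.36, adjusted p 0.00256; adjusted p = 0.268 with an estimated correlation), with 4 members higher adjusted over the list alone and 0 over all genes. Sarcomere genes were lower (13 of 13 below 0, median -0.22, adjusted p 0.00787; adjusted p = 0.798 with an estimated correlation) and so were glycolysis genes (14 of 17 below 0, median -0.16, adjusted p 0.00667; adjusted p = 0.667 with an estimated correlation), and for both the exact permutation test gave an adjusted p of 0.0465. Adjusted over the list alone 3 glycolysis genes passed lower. Without coarse 1 the difference of the list mean shrank from -0.25 to -0.13 for sarcomere and from -0.23 to -0.14 for glycolysis genes. Without the 7 arrays, coarse 1 among them, both were still called by camera, sarcomere genes with 11 of 13 below 0, a median of -0.13 and an adjusted p of 0.0194, and glycolysis genes with 11 of 17, -0.13 and 0.00789. For both adjusted p = 0.284 with an estimated correlation, and the exact permutation test then gave adjusted p of 0.114 and 0.0683, with no p under 0.00794 possible. Fatty acid oxidation genes and PPAR targets were higher with coarse than with fine particles in the 20 arrays (28 of 30 positive, median 0.29, adjusted p 3.82e-11; adjusted p = 0.284 with an estimated correlation), with 3 members called and 8 passing adjusted over the list alone. Ribosomal protein genes were lower (46 of 55 below 0, median -0.12, adjusted p 5.17e-07; adjusted p = 0.409 with an estimated correlation), while in all 27 arrays 45 of 55 were positive, with an adjusted p of 0.0503.

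The most probes of the 6 comparisons were called between fine and ultrafine particles. Tuba8 was 1.90-fold higher with fine particles, with a standard error of 0.16 and an adjusted p of 0.0101, and Atcay, Fbxl22, Ddn and Ndufs6-ps1 were higher by 0.86, 0.80, 0.54 and 0.48. Txnip was 1.89-fold lower, and Cyp2e1, Sat1, which acetylates polyamines, Epb41 and Acot1 stood at -0.66, -0.57, -0.56 and -0.53, each lying on its side of the ultrafine mean in 6 of 6 fine arrays, with adjusted p up to 0.0463. The count was 23, 12 higher and 11 lower with fine particles, with 1408 at an unadjusted p under 0.05. It was 7 without fine 4, 8 without fine 5, 10 without fine 1, 12 without ultrafine 2 and 15 without fine 3, ultrafine 1 or ultrafine 3, and 60 without ultrafine 8, 61 without coarse 1, 62 without ultrafine 4 and 168 without ultrafine 5. For the 20 arrays the count was 129, 68 higher and 61 lower. Tuba8 was higher with fine particles by 0.89, Slc2a4 by 0.76, Fbxl22 by 0.73, Tuba4a by 0.69 and Atcay by 0.68. Pdk4 was 3.30-fold lower, Rbp7 2.40-fold lower, and Txnip, Angptl4 and Sult1a1, a sulfotransferase, stood at -1.10, -0.90 and -0.82, with adjusted p from 3.26e-05 to 0.0438 and 5 of 5 arrays each. That count ran from 73 without ultrafine 3 over 80 without ultrafine 1, 81 to 84 without fine 5, 6, 4 or 1, up to 331 without ultrafine 5.

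Between fine and ultrafine particles 12 lists were called in all 27 arrays and 7 in the 20 arrays. Genes of glycolysis and glucose uptake were higher with fine particles in both. In all 27 arrays 14 of 17 were positive (median 0.39, adjusted p 4.35e-05; adjusted p = 0.301 with an estimated correlation), with 7 passing adjusted over the list alone and 0 over all genes. As many, 14 of 17, were positive in the 20 arrays (median 0.13, adjusted p 0.000256; adjusted p = 0.166 with an estimated correlation), with Slc2a4, Hk2, Eno3 and Pgam2 called, 5 passing adjusted over the list alone and a fry adjusted p of 0.0076. Fatty acid oxidation genes and PPAR targets were lower with fine than with ultrafine particles in the 20 arrays (26 of 30 below 0, median -0.26, adjusted p 3.12e-09; adjusted p = 0.322 with an estimated correlation), with 7 called and 9 lower adjusted over the list alone. Glucocorticoid-responsive genes were lower too (10 of 12 below 0, median -0.39, adjusted p 0.000111; adjusted p = 0.322 with an estimated correlation), with 2 called, 4 lower adjusted over the list alone and a fry adjusted p of 0.0467.

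Between coarse and ultrafine particles no gene passed the test. The limma count was 0 in all 27 arrays, with 299 probes at an unadjusted p under 0.05 and a lowest adjusted p of 0.999, and 0 with array weights or a trend and robust fit. It was 0 in the 20 arrays too, with 884 probes at an unadjusted p under 0.05 and a lowest adjusted p of 0.646, and 1 without ultrafine 6. The skeletal muscle list was higher on 8 of 8 members with coarse particles in all 27 arrays (adjusted p 0.000491, or adjusted p = 0.984 with an estimated correlation). It is the list for which coarse 6 stood far above the other coarse arrays. Without coarse 6 the difference of its mean turned from 0.35 to -0.02. No list was called in the 20 arrays. The bars of probes called set the 6 comparisons side by side.

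**Figure D4:**
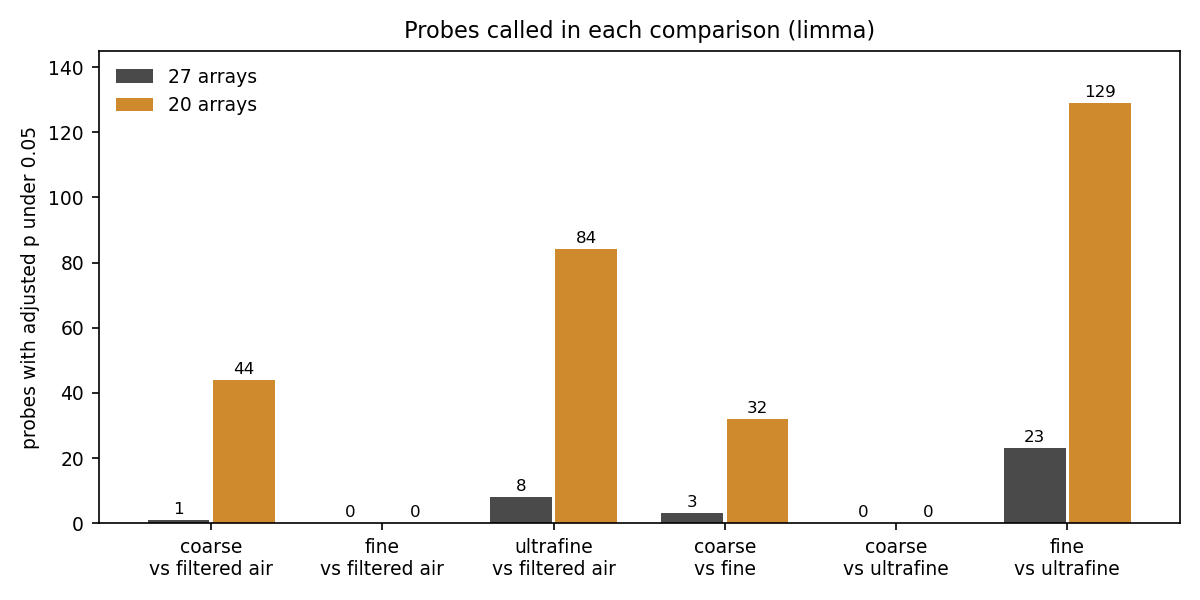
Number of probes with adjusted p under 0.05 by limma (vertical axis) in each of the 6 comparisons (horizontal axis), as a pair of bars for the 27 arrays and the 20 arrays. The counts were 1 and 44 for coarse against filtered air, 0 and 0 for fine, 8 and 84 for ultrafine, 3 and 32 for coarse against fine, 0 and 0 for coarse against ultrafine, and 23 and 129 for fine against ultrafine.

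Probes differing anywhere among the 4 groups numbered 11 in all 27 arrays, with 807 at an unadjusted p under 0.05, and 97 in the 20 arrays. Without the 7 arrays 20 probes were called higher and 10 lower with both coarse and ultrafine particles, out of 29 and 56 higher and 15 and 28 lower, where independent lists of these sizes would share 0.139 and 0.036. Both comparisons use the same filtered air arrays, which alone can make calls coincide. Across all probes, which are not independent replicates, the log2 differences of coarse and ultrafine particles from filtered air correlated with Pearson r = 0.704 and Spearman rho = 0.629 in all 27 arrays. Unchanged simulated groups that shared their controls gave a median r of 0.448, and 27 of 100 draws reached the observed r. Coarse and fine particles gave r = 0.302 with rho = 0.276, and fine and ultrafine r = 0.131 with rho = 0.14, where 66 and 78 of 100 draws were as high. With separate control arrays for each side, the median r was 0.402 for coarse and ultrafine, 0.09 for coarse and fine and -0.05 for fine and ultrafine. Leaving out 1 array at a time, r of coarse and ultrafine ran from 0.44 to 0.826, of coarse and fine from 0.206 to 0.514, and of fine and ultrafine from -0.02 to 0.368. Without the 7 arrays r was 0.539 for coarse and ultrafine, 0.393 for coarse and fine and 0.371 for fine and ultrafine, with rho of 0.429, 0.362 and 0.404, and 37, 69 and 68 of 100 draws were as high. With separate control arrays the median r was then 0.283, 0.184 and 0.135, and leaving out 1 of the 20 arrays r ran from 0.369 to 0.623, 0.207 to 0.517 and 0.104 to 0.49.

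A panel of 20 genes of heart load, oxidative stress, inflammation and vessel tone was followed whatever its values. Cyp1a1, the classic target of the aryl hydrocarbon receptor, at a mean of 5.72, and the cytokine genes Il6, at 5.68, and Tnf, at 5.72, lay below the filter on dim probes. No panel gene was called against filtered air in all 27 arrays, including the natriuretic peptide genes Nppa and Nppb, the myosin genes Myh6 and Myh7, the antioxidant genes Nqo1, Gclc, Sod2 and Cat, and Ccl2, Icam1, Ace, Agtr1a, Nos3 and Edn1. Hmox1 was called in the 20 arrays with ultrafine particles, and stood at 0.34 with an adjusted p of 0.0749 with coarse particles.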

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

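The 3 tests of where the lymphocyte signal came from and the test of time of day were chosen only after the result was seen, and the tests of the fatty acid genes were run on a set of 20 arrays that was itself chosen after seeing the data. A sample is listed here when it lay far from the other samples of its group, by the gap to its nearest neighbour over the range of the group. Of 144 groups of values tested, 16 (11.1%) had such a sample, where chance gives about 1 in 20, and 9 of the 16 were coarse 1.

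On coarse 1 the list means were low for calcium handling genes, at 7.27 against 7.85 to 7.97 on the other coarse arrays, for collagens and matrix genes, at 7.39 against 7.93 to 8.24, for the respiratory chain, at 11.2 against 11.90 to 12.26, for sarcomere genes, at 11.35 against 12.04 to 12.16, for fetal and hypertrophy genes, at 10.39 against 11.36 to 11.77, for fibroblast markers, at 8.55 against 9.21 to 9.43, and for glycolysis, at 8.97 against 9.46 to 9.59. Tuba8 on coarse 1 stood at 7.16 against 8.09 to 8.46, and Atcay at 6.11 against 6.81 to 7.21. On ultrafine 7 Tuba8 stood at 7.41 against 7.90 to 8.34 and Myo16 at 5.43 against 5.68 to 5.84. On filtered air 1 the lymphocyte list stood at 7.36 against 6.20 to 6.42, ribosomal proteins at 11.54 against 11.05 to 11.21 and the respiratory chain at 11.83 against 12.08 to 12.18. Skeletal muscle markers stood at 9.89 on coarse 6 against 7.53 to 7.75, and at 8.40 on ultrafine 5 against 7.39 to 7.73.

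Lymphocyte markers were high on 6 of the 27 arrays, in all 4 groups. A list of thymocyte genes, written before the test, was read on them. The mean of its 8 T lineage genes lay over 3 median absolute deviations above the median on 6 of 6 arrays, at 9.58 to 20.99. It also did so on coarse 5, at 4.16, and fine 4, at 3.90, which stay in the 20 arrays. Of 5 genes of immature thymocytes 3 were measured, Rag1, Dntt and Arpp21. Rag1 and Dntt had already been seen high on these 6 arrays, so the mean of the 3 in part restates that. Arpp21 stood at 6.11 to 7.96 on the 6, against a median of 5.72. The mean of the 3 lay over the limit on 6 arrays, with scores of 5.84 to 17.21, and on coarse 5, at 3.10. The lowest of these scores, 5.84, argues against blood or lymph node lymphocytes alone, which lack these genes, and the 5 genes of cytotoxic and NK cells were over the limit on 0 of 6 arrays, though Prf1 among them stood at 7.81 to 8.39 on the 6 against a median of 7.31, and the 2 measured B cell genes were over it on 5. Filtered air 1 is among the 6, so the signal also occurred without particles, on 1 array. That was known when the test of particle exposure as the whole cause was chosen, so the test adds nothing to it. Thymus tissue carried along with the heart is a candidate source, alone or with lymph node beside it, and whether exposure changed how much of it was carried along was not tested.

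In the 20 arrays fatty acid oxidation genes and PPAR targets were higher with coarse and with ultrafine particles than with filtered air by camera at its preset correlation, but the list was not called with an estimated correlation (adjusted p = 0.531 and 0.577) or by fry (0.215 and 0.291). By camera at the preset correlation, the list kept adjusted p of at most 2.40e-05 with the thymocyte mean as a covariate. With the adipocyte list mean as a covariate it kept at most 3.14e-06. These p-values do not measure the spread of the list mean between rats, so they cannot decide whether thymus or adipose tissue was the cause. The median of the list was 0.18 before and 0.24 and 0.17 after for coarse particles, and 0.12 before and 0.09 and 0.11 after for ultrafine particles. Adjusting for either mean thus did not take the shift of the list away. A different time of day at sampling could move Pdk4 and its companions: 0 circadian genes were called over their list alone in both comparisons, but the intervals of Per2, -0.71 to 0.43 and -0.96 to 0.11, are wide, and Bhlhe40 stood at -0.36 with ultrafine particles with an adjusted p of 0.0113 over the list alone. Time of day at sampling cannot be told apart from exposure with these values, since no sampling times are given, and the exposure itself stays open beside it.

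Regroupings of the arrays, 100 for each count with the real one among them, show how many groupings of the same sizes reached the real count. A low share makes chance alone less likely for a count but does not exclude it. The shares were not adjusted over the counts, and none under 1 of 100 was possible. In all 27 arrays at most 3 of 100 reached the following probe counts. For coarse against filtered air 1 did (real 1, highest other 0), for ultrafine against filtered air 1 (real 8, highest other 1) and for coarse against fine 1 (real 3, highest other 1). For fine against ultrafine 1 did (real 23, highest other 0) and for any difference 3 (real 11, highest other 689). Where the real count was 0, for fine against filtered air (100, highest other 0) and coarse against ultrafine (100, highest other 4204), every grouping reaches it, so this test says nothing about chance. In the 20 arrays, chosen after seeing the data, at most 3 of 100 reached the following counts. For coarse against filtered air 1 did (real 44, highest other 3), for ultrafine against filtered air 2 (real 84, highest other 1963) and for coarse against fine 1 (real 32, highest other 3). For fine against ultrafine 3 did (real 129, highest other 1327) and for any difference 2 (real 97, highest other 574). The test again says nothing where the real count was 0, for fine against filtered air (100, highest other 1) and coarse against ultrafine (100, highest other 992). Groupings that call many times the real number of probes, up to 4204, point to a structure of the samples that the groups do not hold, in the 20 arrays as well, up to 1963. For the counts of lists of coarse and ultrafine particles chance cannot be excluded: in all 27 arrays 67 groupings reached the real 9 for coarse (highest other 18) and 45 the real 11 for ultrafine (highest other 22), and in the 20 arrays 43 reached the real 7 (highest other 21) and 68 the real 6 (highest other 16). For fine particles, with a real count of 0 lists, all 100 reached it in each set (highest other 12 and 17), which says nothing.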

How the results depend on the processing

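The exclusions of arrays, the thymocyte covariate and every fit of the 20 arrays were chosen after seeing the data. Counts are given in the order coarse, fine and ultrafine against filtered air, coarse against fine, fine against ultrafine, and any difference, only where they moved by over 1.5 times from 1, 0, 8, 3, 23 and 11; coarse against ultrafine stayed at 0 in every setting run on 27 arrays. With no filter ultrafine gave 4 and coarse against fine 1. In the probes above the median level, with fewer probes tested, ultrafine gave 3, fine against ultrafine 13 and any difference 6. Cyclic loess gave 2 for coarse, 8 for coarse against fine, 50 for fine against ultrafine and 27 for any difference. A trend with robust fitting gave 0 for ultrafine. Array weights gave 126, 19, 86, 55, 815 and 394, with the lowest weights on ultrafine 8 (0.135), ultrafine 7 (0.139) and coarse 1 (0.151). With the replicate number as a random block the counts were 2 for coarse, 6 for coarse against fine, 54 for fine against ultrafine and 30 for any difference. With it as a fixed block they were 9, 9, 51 and 25, while ultrafine gave 12, 2 higher and 10 lower, with 2 of its 8 calls kept. The labels do not say that numbers pair rats, and the correlation within a block was 0.135. With group means removed, arrays of other groups that shared a number correlated at a median r of 0.341 (-0.717 to 0.873). Those of other numbers gave 0.008 (-0.828 to 0.923). In the 20 arrays the medians were 0.156 and -0.014. What the numbers stand for was not tested, and the regroupings did not keep them. Fits of the compared groups alone gave 0 for coarse, 1 for ultrafine and 5 for fine against ultrafine, with fewer arrays behind the spread. Without the 6 lymphocyte-high arrays the counts were 21 for coarse, 55 for ultrafine, 8, 72 and 56, without the 7 arrays that stood apart 44, 84, 32, 129 and 97, without the 6 picked by eye (filtered air 1, coarse 1 and 2, ultrafine 2, 7 and 8) 37, 72, 49, 140 and 138, and with the thymocyte mean as a covariate 14, 29, 15, 153 and 62. A fold over 1.5 with a false discovery rate under 5% gave 2 for ultrafine and 5 for fine against ultrafine, and under 25% 3 for coarse, 5 for coarse against fine and 67 for fine against ultrafine. Leaving out 1 array at a time, the counts ran from 0 to 3, 0 to 0, 0 to 21, 0 to 8, 7 to 168 and 10 to 27: coarse was 0 without filtered air 2 or 3 or coarse 1, 2, 3, 5 or 6, 2 without filtered air 1 and 3 without ultrafine 8, and any difference was 21 without coarse 1, 22 without ultrafine 5, 24 without ultrafine 7 and 27 without ultrafine 8. Counts of lists against filtered air ran from 6 to 15 for coarse (15 without coarse 5), 0 to 1 for fine (1 without filtered air 5, fine 1 or fine 3) and 8 to 19 for ultrafine (19 without ultrafine 6, 17 without ultrafine 8). An estimated correlation, fry and the exact permutation test gave 0 lists for coarse and for ultrafine, and ultrafine gave 6 lists without the 7 arrays. The correlation of fine and ultrafine log2 differences turned from 0.131 to -0.0542 with separate control arrays for each side, which removes the shared controls and also leaves fewer control arrays on each side, and in the 20 arrays it went from 0.371 to 0.135. In the 20 arrays the counts were 140, 0, 117, 121, 1056 and 514 with array weights, 35, 0, 67, 28, 97 and 68 with a trend and robust fit, 59, 0, 102, 37, 187 and 157 with the block, and any difference gave 192 without ultrafine 5. Of 44 list calls over all comparisons in 27 arrays and 29 in the 20 arrays, 0 changed direction with arrays centred on their medians or by cyclic loess, and 33 and 28 stayed called by cyclic loess; the median log2 difference of all probes stayed within 0.01 of 0 under each. Of 9743 values of 233 named genes and comparisons, 0 called ones reversed, 126 uncalled ones changed sign, 222 lost a call and 334 gained one. Where no reason is named, the cause was not tested. No pseudocount was run because the values are on a log2-like scale, and signal over background was not analysed here for want of background values. List tests between sizes were run without the 7 arrays but not with 1 array left out at a time.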

Other observations

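Markers of tissues other than ventricular muscle varied between arrays, also between those of 1 group. Ucp1, the uncoupling protein of brown fat, ran from 5.54 on coarse 3 to 11.3 on filtered air 5. The skeletal muscle troponin gene Tnnt3 stood at 8.65 on coarse 6 and at most at 6.82 on any other array. Npy, a neuropeptide of sympathetic neurons, stood at 10.49 on ultrafine 5 and 9.63 on fine 2. Nppa, an atrial natriuretic peptide gene, stood at 8.58 on ultrafine 2 against a mean of 11.7 over all arrays.

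Among the 27 arrays the first principal component held 49.9% of the variance, the second 17.1% and the third 10.8%. The pair of arrays most alike, ultrafine 1 and ultrafine 3, correlated at 0.996 and shared 31 identical values, and the pair least alike at 0.821.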
